A study of Mus musculus with 31 samples.

How the data were processed

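Small RNA was sequenced from the right hippocampus of C57Bl/6 J mice that were wild type (WT) or lacked the serotonin transporter (5-HTT knockout, KO). Mice received water, 4 weeks of exercise or corticosterone, the main glucocorticoid stress hormone of rodents. Per the labels' protocols, total RNA was enriched for small RNA, ligated to adapters with the Ion Total RNA-Seq Kit v2, barcoded and sequenced on an Ion Torrent S5. The labels name the replicates of each group as biological replicates, so each library was taken as 1 animal.

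The authors deposited 5 tables of whole-number read counts, 1 for each pair of groups, over the same 1966 mature microRNAs. Per the submitters' processing notes, cutadapt 2.3, BWA, Subread, featureCounts and limma 3.54.1 were used with the GRCm38 (mm10) build. The notes give no order or role for these tools, and whether reads were counted by strand is not given in the sources used here. The values were treated as counts per microRNA that had not been normalized: they are whole numbers, and their totals differ between libraries. Libraries present in more than 1 table had identical counts in each. Of the 1966 microRNAs, 391 had no count in any library. Every column was matched to a sample through the sample code in the labels, and the number of other columns of per-sample values was 0.

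Total counts ranged from 1011285 to 4052174 per library over 31 libraries. The total is of counts assigned to mature microRNAs, and the number of sequenced reads is not given in the sources used here. Within each group no pair of libraries agreed within sampling noise: the lowest chi-square per degree of freedom was 16.1, so each library counted as 1 replicate. The targeted transporter mRNA is not among the measured features, so the genotype labels could not be checked from these counts. The first letter of the sample code, G or H, has no stated meaning and was tested as a possible batch. The number after the letter has no stated meaning either and was not tested. The barcode kit named in the labels holds fewer barcodes than there were libraries, so the libraries must have been sequenced in more than 1 pool, and no label names the pool.

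Each comparison was fitted on the libraries of its own deposited table with edgeR 4.0.16 in R 4.3.3. The steps were filterByExpr by group, TMM scaling, estimateDisp, glmQLFit with robust estimation and the quasi-likelihood F test. Benjamini-Hochberg adjustment ran over the microRNAs tested in that comparison, and a microRNA was called at an adjusted p below 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM values are counts divided by TMM-scaled library sizes (cpm in edgeR) within the table of the comparison, given as mean ± SD. The table of KO-water and WT-water held only 3 of the 6 KO-water libraries. Its remaining knockout column belongs to a KO-exercise sample by the labels, so that column was left out. Genotype-by-treatment interactions were tested in joint fits of the 4 groups involved. Across genotypes, log2 fold changes were correlated over microRNAs. The correlation of differences in mean log2 CPM was set against 100 shuffles of the group labels within each genotype.

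Fixed lists of microRNAs covered neuron-enriched, activity-regulated, oligodendrocyte, microglia and immune cell, vessel, red blood cell, muscle, hindbrain and spinal cord, choroid plexus and ciliated cell, and epithelial or sensory (miR-200 family and miR-183 cluster) microRNAs. Further lists held the miR-379/miR-410 and miR-127/miR-433 clusters of the imprinted Dlk1-Dio3 locus, the Htr2c intronic microRNAs, the let-7 and miR-98 family, the miR-17/92 and paralogous clusters, the miR-34 family, the miR-29 and miR-30 families, and microRNAs reported to target the serotonin transporter or the glucocorticoid receptor. Lists of other small RNA classes had no member in these tables. Lists with at least 3 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01, two-sided. Estimated correlations and fry were alternatives. Adjustment ran over the lists of 1 comparison.

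The groups, tests, lists and most alternatives were fixed before the data were examined, as was the rule for named microRNAs. Per comparison the rule took all called microRNAs if 24 or fewer, otherwise the 12 with the largest absolute log2 fold change in each direction. With fewer than 10 calls it also took the 5 with the smallest p in each direction. It added, of each list, the 2 most abundant and all called members, a fixed set (miR-124-3p, miR-132-3p, miR-212-3p, miR-34a-5p, miR-16-5p, miR-135a-5p, miR-18a-5p, miR-146a-5p, miR-9-5p, miR-451a and the targeted gene Slc6a4, which was not counted), and the 5 most abundant microRNAs. Other settings were DESeq2 1.42.0 and its size factors, library sizes without scaling factors, limma-voom, no filter on low counts, a mean of at least 10 CPM, a joint fit of all 6 groups, the replicate number as a block, the code letter as a covariate or as a restriction, non-robust estimation, and leaving out each library in turn. Alternatives chosen after seeing the data were other sets of KO-water libraries and a covariate for the first axis of within-group variation. That axis is the first principal component of log2 CPM after removal of the group means, and every library's own profile was then scored on it.

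Hairpin positions were taken from GRCm38 annotation by name. Of 1575 microRNAs with counts, 1530 matched an annotated hairpin and 1450 matched 1 hairpin only. Counting intervals of ratios are exact 95% conditional binomial intervals on pooled counts. They cover counting error only, since reads without molecular identifiers are not independent molecules. The fitting scripts were tested on simulated counts with 200 changed microRNAs per comparison. For KO-water against WT-water, 71.6% of changes of 2-fold were recovered, against 92.5% for WT exercise, 86.6% for WT corticosterone, 67.2% for KO exercise and 18.2% for KO corticosterone. False calls were between 2.33% and 4.32% of the calls. The simulated microRNAs varied independently, without the axis of within-group variation of the real libraries. These shares of false calls therefore do not carry over to the real data.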

Results

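MicroRNA profiles were obtained from 31 right hippocampi in 6 groups: WT-water (n = 7), WT-exercise (n = 5), WT-corticosterone (n = 6), KO-water (n = 6), KO-exercise (n = 5) and KO-corticosterone (n = 2). The design asks how the hippocampal small RNA profile responds to exercise and to a raised stress hormone, and whether the response depends on the serotonin transporter. The mean total count per library was 2830878 ± 837148 in WT-water, 1833409 ± 342167 in WT-exercise and 1920854 ± 341326 in WT-corticosterone (SD). The corresponding totals were 2206397 ± 649323 in KO-water, 1880805 ± 774789 in KO-exercise and 2010774 ± 483979 in KO-corticosterone. A median of 924 microRNAs was detected per library. MiR-124-3p, the most abundant neuronal microRNA, took 24.4% ± 2.09 of all counts (SD, n = 31), and its mean share per group lay between 23.6% and 24.8%. The 5 most abundant microRNAs of each library together held 44.2% of its counts on average.

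In the comparison of genotypes under water, 3 of the 6 KO-water libraries were set against 7 WT-water libraries. The calls did not extend to the other KO-water libraries: between those and WT-water edgeR called 0 microRNAs. MiR-219a-5p, a microRNA of the oligodendrocyte lineage, fell from 1049 ± 127 CPM in WT-water to 60.4 ± 12.5 CPM in KO-water, a log2 fold change of -4.10 ± 0.17 (SE). MiR-342-3p, encoded in an intron of Evl, rose from 2391 ± 351 to 13962 ± 2078 CPM, a log2 fold change of 2.55 ± 0.13. MiR-218-5p, which is enriched in neurons and hosted by Slit2 and Slit3, rose by 2.09 ± 0.12 to 69891 ± 11191 CPM. For these 3 microRNAs every KO-water library of the table lay outside the WT-water range. Adjusted p was 1.77e-09 for miR-219a-5p, 6.83e-09 for miR-342-3p and 8.38e-09 for miR-218-5p (edgeR quasi-likelihood, Benjamini-Hochberg).

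Among the fixed set, miR-16-5p (1.65 ± 0.12) and miR-135a-5p (1.11 ± 0.14), both reported to target the serotonin transporter, rose in these KO-water libraries. MiR-146a-5p, which restrains inflammatory signalling, fell by 1.36 ± 0.26 on the log2 scale, miR-9-5p by 0.75 ± 0.17 and the erythroid miR-451a by 1.54 ± 0.24. MiR-124-3p (0.35 ± 0.12) and miR-18a-5p (0.47 ± 0.16) were called, with adjusted p of 0.0267 and 0.0182 by edgeR. The other microRNAs with the largest rises were miR-182-5p (2.44), miR-145b (2.32), miR-152-3p (2.305), miR-421-3p (2.28), miR-503-3p (2.27), miR-192-5p (2.20), miR-551b-5p (2.18), miR-187-5p (2.03), miR-935 (2.00) and miR-223-3p (1.99). Large falls were measured for miR-677-5p (-3.55), miR-677-3p (-3.53) and miR-1298-5p (-5.70 ± 1.57), the last encoded in an intron of the serotonin receptor gene Htr2c and ranging from 61.7 to 1432 CPM among the WT-water libraries. For 8 further microRNAs that fell, the KO-water libraries held few counts in total, and ratios of rates are given in place of fitted folds. MiR-574-5p was 23.5 times lower in KO-water (95% interval 4.10 to 939, from 1 count), miR-202-5p 20.0 times (5.43 to 167, 2 counts) and miR-499-5p 15.6 times (5.23 to 76.2, 3 counts). MiR-450a-5p was 13.0 times lower (5.90 to 35.7), miR-362-5p 10.6 times (5.07 to 26.6), miR-205-5p 10.4 times (3.48 to 51.4), miR-21a-3p 10.1 times (3.35 to 49.6) and let-7a-2-3p 9.27 times (4.19 to 25.6).

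Members of most lists moved in both directions. Of 26 neuron-enriched microRNAs, 10 rose and 8 fell, with miR-138-5p up by 1.10 ± 0.11 and miR-128-3p at -1.05 ± 0.12. Of 11 oligodendrocyte microRNAs, 4 rose and 3 fell, among them miR-338-3p at -1.92 ± 0.13. Other arms of the miR-338 and miR-219a hairpins did not fall with them between the 3 KO-water libraries of the table and the other 3. In that contrast miR-338-3p was at -1.81 ± 0.19 and miR-338-5p at 1.16 ± 0.16. MiR-219a-5p was at -3.72 ± 0.22, miR-219a-1-3p at 2.22 ± 0.52 and miR-219a-2-3p at 0.18 ± 0.16, the last not called (adjusted p 0.359 by edgeR). Of 10 microglia and immune cell microRNAs, 4 rose and 2 fell, with the lymphoid miR-150-5p at 1.80 ± 0.13. Of 9 vessel microRNAs, 4 rose and 1 fell, with the endothelial miR-126a-3p at 1.39 ± 0.11. All 5 red blood cell microRNAs were called, 3 up and 2 down, with miR-486a-5p at 1.62 ± 0.17 against -1.54 for miR-451a. In the imprinted Dlk1-Dio3 locus, 14 of 60 members of the miR-379/miR-410 cluster rose and 24 fell, and 8 of 20 members of the miR-127/miR-433 cluster rose and 9 fell. From these clusters, miR-409-3p rose by 1.80 ± 0.12 and miR-434-3p stood at -2.10 ± 0.11. Of 18 members of the miR-29 and miR-30 families, 1 rose and 7 fell, with miR-29b-3p at -0.62 ± 0.15. Of 23 let-7 and miR-98 members 7 rose and 10 fell, of 14 members of the miR-17/92 and paralogous clusters 4 rose and 4 fell, and of 22 activity-regulated microRNAs 5 rose and 6 fell. Of 15 microRNAs reported to target the serotonin transporter 6 rose and 3 fell, and of 11 reported to target the glucocorticoid receptor 4 rose and 3 fell. Among 7 miR-34 family members 2 rose, among 5 muscle microRNAs 2 fell, and among 17 choroid plexus and ciliated cell microRNAs 4 rose and 3 fell. The 9 Htr2c intronic microRNAs had 2 rises and 2 falls, the 6 members of the miR-200 family and miR-183 cluster 1 of each, and neither of the 2 hindbrain and spinal cord microRNAs was called. Adjusted over the list alone, 5 miR-29 and miR-30 members fell, 8 let-7 members rose, 5 members of the miR-17/92 list rose and 5 fell, 3 choroid plexus microRNAs rose and 2 fell, and 1 Htr2c microRNA rose. The other counts were the same adjusted over the list alone.

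In total 192 microRNAs rose and 162 fell among 581 tested (edgeR quasi-likelihood, adjusted p below 0.05), and 208 of the calls exceeded 2-fold. The groups did not overlap for 312 of the 581 microRNAs, where chance gives 1.67% of them. No list was called by camera (lowest adjusted p 0.697), 0 lists had an unadjusted p under 0.05, and fry, which asks whether the members move 1 way on balance, called 13. The genotype calls held for the 3 KO-water libraries in the deposited table: with all 6 KO-water libraries edgeR called 0 microRNAs (179 at an unadjusted p under 0.05), and with only the other 3 it called 0 (24 at an unadjusted p under 0.05). With only the other 3, miR-182-5p, miR-145b, miR-503-3p, miR-223-3p, miR-135a-5p, miR-9-5p, miR-29b-3p, miR-486a-5p and miR-126a-3p had the opposite sign. In a joint fit of all 6 groups 54 rose and 15 fell. Without scaling factors 140 rose and 224 fell, as the median log2 fold change of all microRNAs moved from 0.03 to -0.30, while DESeq2 gave 176 and 187, and its size factors in edgeR 173 and 180. MiR-124-3p lost its call in 9 of the fits that left out 1 library and miR-18a-5p in 8. The log2 fold change of miR-18a-5p was 0.16 without KO-water 4 and 0.30 without WT-water 6. That of miR-124-3p was 0.17 without KO-water 6, 0.22 without KO-water 4, and 0.21, 0.20, 0.23 and 0.21 without WT-water 3, 4, 5 and 7. Without KO-water 3 the fitted values of miR-574-5p (-6.50), miR-499-5p (-7.45) and let-7a-2-3p (-4.81), which depend on the prior count, lay further from 0 than with it (-4.01, -3.57 and -2.94).

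**Figure D1:**
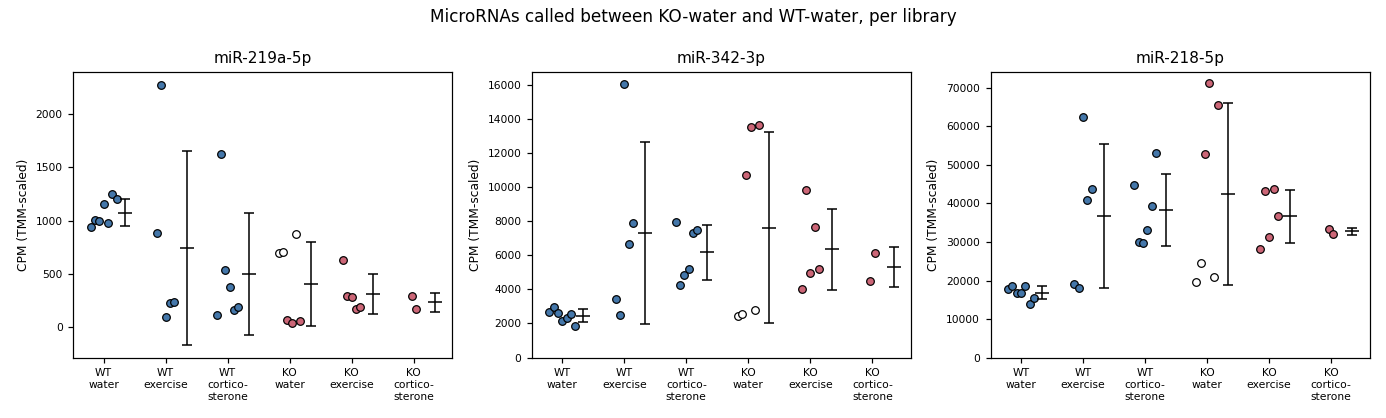
CPM (TMM-scaled over all libraries, vertical axis) of miR-219a-5p, miR-342-3p and miR-218-5p in each library of the 6 groups (horizontal axis), with points for libraries and lines for the mean and SD. Open points are the 3 KO-water libraries that are not in the table of the genotype comparison, which lay beside or close to the WT-water libraries, while the 3 filled KO-water points lay apart from both.

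The effect of exercise in WT mice was tested between 5 WT-exercise and 7 WT-water libraries. MiR-132-3p and miR-212-3p, which share a precursor transcript induced by neuronal activity, rose together. MiR-132-3p went from 2602 ± 370 to 5680 ± 839 CPM (log2 fold change 1.13 ± 0.14) and miR-212-3p from 1330 ± 157 to 2237 ± 163.2 CPM (0.75 ± 0.12), each in 5 of 5 exercise libraries above every water library. Their hairpins lie on chromosome 11 at 75173682 to 75173747 (Mir132) and 75173388 to 75173478 (Mir212), GRCm38, plus strand, within the noncoding transcript 1700016P03Rik. MiR-130a-3p rose by 1.40 ± 0.19, miR-194-5p by 1.71 ± 0.22 and miR-16-5p by 1.60 ± 0.25. Adjusted p by edgeR was 0.000134 for miR-132-3p, 0.000974 for miR-212-3p and miR-16-5p, 0.000229 for miR-130a-3p and 0.000194 for miR-194-5p.

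MiR-126b-5p and miR-122b-3p were almost absent from WT-water and present in every WT-exercise library. MiR-126b-5p had 2 counts in the 7 water libraries and 668 in the 5 exercise libraries, a ratio of rates of 722 (95% counting interval 199 to 5974). MiR-122b-3p had 42 and 1114 counts, a ratio of 57.3 (42.1 to 80.01). Adjusted p by edgeR was 8.43e-07 and 7.31e-06. Mir126b lies on chromosome 2 at 26591363 to 26591420, minus strand, opposite Mir126a within the endothelial gene Egfl7, and Mir122b on chromosome 18 at 65248863 to 65248921 overlaps Mir122. Reads of a hairpin and an overlapping hairpin on the other strand can be told apart only if strand was used in counting. MiR-196b-5p, encoded in the Hoxa cluster, did not pass the count filter here: it had 0 counts in 7 water libraries and 100 in 5 exercise libraries, at least 57.5-fold higher by the exact 95% interval (72.1-fold against a floor of 3 counts over the group).

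Other large rises with exercise were miR-182-5p (2.34), miR-152-3p (1.83), miR-342-3p (1.61), miR-3059-5p (1.51), miR-466n-5p (1.41), miR-409-3p (1.40) and miR-325-5p (1.35). The largest falls were miR-1298-5p (-3.13), miR-3084-3p (-2.15), miR-677-5p (-1.77), miR-677-3p (-1.77), miR-23b-5p (-1.70), miR-2137 (-1.57), let-7a-2-3p (-1.52), miR-331-3p (-1.50), miR-199b-5p (-1.47), miR-150-3p (-1.45), miR-1298-3p (-1.38) and miR-501-5p (-1.34). MiR-135a-5p (0.87 ± 0.17) and miR-18a-5p (0.41 ± 0.15) rose, and miR-451a stood at -1.03 ± 0.34. Of 22 activity-regulated microRNAs 7 rose and 3 fell, and adjusted over the list alone 8 rose and 4 fell. Of 23 let-7 and miR-98 members 8 rose and 6 fell, with let-7b-5p at 0.94 ± 0.19 and let-7b-3p at 1.18 ± 0.19. Of 26 neuron-enriched microRNAs 4 rose and 5 fell, with miR-218-5p at 1.17 ± 0.27 and miR-128-3p at -0.70 ± 0.20. Of 10 vessel microRNAs 5 rose and none fell, or 5 and 1 adjusted over the list alone, with miR-126b-5p among the rises and miR-126a-3p at 0.53 ± 0.19. Of 9 microglia and immune cell microRNAs 4 rose and 1 fell, or 5 and 1 adjusted over the list alone, with miR-142a-3p at 0.86 ± 0.17 and miR-146b-5p at 0.85 ± 0.19. Of 9 oligodendrocyte microRNAs 2 fell, including miR-338-3p at -1.13 ± 0.31, and of 18 miR-29 and miR-30 members 2 rose and 1 fell, with miR-30c-5p at 0.70 ± 0.17 (1 and 0 adjusted over the list alone).

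Of the remaining lists, 13 of 59 miR-379/miR-410 members rose and 3 fell (11 and 3 adjusted over the list alone). Of 20 miR-127/miR-433 members 4 rose and 3 fell, of 12 miR-17/92 and paralogous members 3 rose and 1 fell, of 13 microRNAs reported to target the serotonin transporter 4 rose and 2 fell, and of 11 reported to target the glucocorticoid receptor 2 rose and 2 fell. Of 16 choroid plexus and ciliated cell microRNAs 1 rose and 2 fell, and of 8 Htr2c intronic microRNAs 2 fell. Of 5 red blood cell microRNAs 1 rose and 1 fell (2 and 1 adjusted over the list alone). Of 6 members of the miR-200 family and miR-183 cluster and of 7 miR-34 family members 1 each rose, no muscle microRNA of 5 was called, and the 1 hindbrain and spinal cord microRNA tested was called as a fall only when adjusted over the list alone.

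With exercise 110 microRNAs rose and 70 fell among 553 tested in WT mice (edgeR quasi-likelihood, adjusted p below 0.05). The groups did not overlap for 55 of the 553, where chance gives 0.253% of them. Camera called no list (lowest adjusted p 0.813, with 0 lists under an unadjusted p of 0.05) and fry called 3. Within libraries of code letter G 10 microRNAs were called and within code letter H 210, the latter from 2 exercise and 2 water libraries. Those 2 exercise libraries had close scores on the axis of within-group variation (7.64 and 8.38), while the exercise libraries of letter G ranged from -11.7 to 14.5. With the axis of within-group variation as a covariate 15 rose and 12 fell, and 24 of the 180 calls remained, among them miR-132-3p, miR-212-3p, miR-16-5p, miR-130a-3p, miR-126b-5p and miR-122b-3p. In that fit miR-325-5p had the opposite sign (-0.32) and was not called. Without scaling factors 78 rose and 85 fell, as the median log2 fold change of all microRNAs moved from 0.04 to -0.07, and limma-voom gave 92 and 85. Without WT-exercise 3 or 4 the count was 113 or 109, without WT-exercise 5 there were 66 rises and 37 falls, and without WT-exercise 2 it was 274. Calls of miR-182-5p (1.38, adjusted p 0.163 without WT-exercise 4), miR-128-3p (0.0569 and 0.0557 without WT-exercise 4 and 5), miR-2137 (0.0563 and 0.0706 without WT-exercise 3 and 5) and let-7a-2-3p (0.0529, 0.0582 and 0.0619 without WT-exercise 3, 4 and 5) were lost, as were those of miR-325-5p, miR-451a, miR-126a-3p and miR-18a-5p in 6, 6, 7 and 10 of the fits without 1 library. Without WT-exercise 3, which held the highest level of miR-126a-3p in its group, the change of miR-126a-3p was 0.31.

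**Figure D2:**
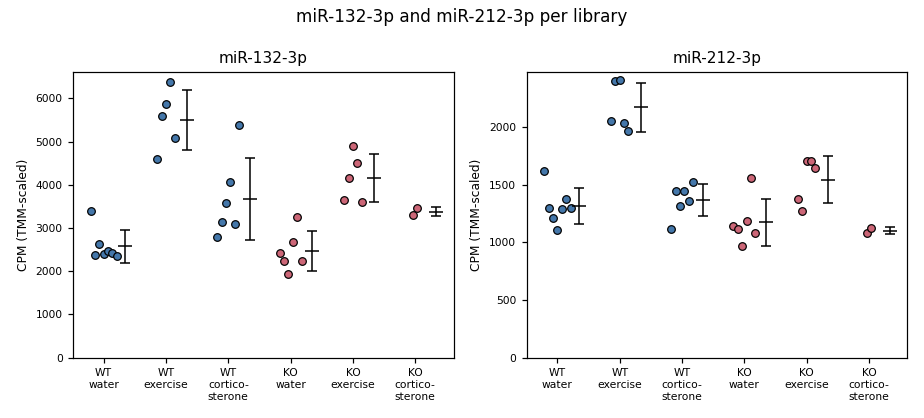
CPM (TMM-scaled over all libraries, vertical axis) of miR-132-3p and miR-212-3p in each library of the 6 groups (horizontal axis), with points for libraries and lines for the mean and SD. All 5 WT-exercise libraries lay above all 7 WT-water libraries for both microRNAs.

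Corticosterone was tested in WT mice between 6 treated and 7 water libraries. MiR-126b-5p and miR-122b-3p were again present in every treated library, with 629 counts against 2 (ratio of rates 541, 95% counting interval 149 to 4475) and 1157 against 42 (ratio 47.4, 34.8 to 66.1). MiR-130a-3p rose from 695 ± 142 to 2056 ± 404 CPM (log2 fold change 1.56 ± 0.16, 6 of 6 libraries above all water libraries) and miR-16-5p by 1.41 ± 0.20. MiR-132-3p rose by 0.58 ± 0.17, while miR-212-3p had a log2 fold change of 0.11 ± 0.12 that did not pass (adjusted p 0.482 by edgeR) and was -0.01 without scaling factors. MiR-34a-5p, a p53-induced microRNA, rose by 0.34 ± 0.12 and miR-135a-5p by 0.86 ± 0.19. MiR-196b-5p had 0 counts in water and 79 in corticosterone libraries, at least 36.0-fold higher by the exact 95% interval (45.3-fold against a floor of 3 counts over the group).

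Other large rises were miR-182-5p (2.00), miR-152-3p (1.86), miR-764-5p (1.65), miR-34c-3p (1.55), miR-194-5p (1.51), miR-325-5p (1.498), miR-3059-5p (1.43) and miR-28a-3p (1.42). The largest falls were miR-362-5p (-2.53), miR-3084-3p (-2.12), miR-501-5p (-1.65), miR-331-3p (-1.57), miR-150-3p (-1.50), miR-2137 (-1.46), miR-199b-5p (-1.45), miR-497a-3p (-1.40), miR-490-3p (-1.40), let-7j (-1.32), miR-339-5p (-1.28) and miR-30d-3p (-1.26). MiR-451a fell by 1.24 ± 0.22 on the log2 scale. Of 9 microglia and immune cell microRNAs 5 rose and 1 fell, with miR-146b-5p at 0.96 ± 0.14. Of 10 vessel microRNAs 5 rose and none fell, or 5 and 1 adjusted over the list alone, with miR-126b-5p among the rises and miR-126a-3p at 0.56 ± 0.16. Of 7 miR-34 family members 3 rose, including miR-449a-5p at 1.17 ± 0.20, and of 16 choroid plexus and ciliated cell microRNAs 3 rose. Of 26 neuron-enriched microRNAs 5 rose and 5 fell, with miR-218-5p at 1.26 ± 0.17, miR-138-5p at 0.52 ± 0.16 and miR-128-3p at -0.59 ± 0.19. Of 9 oligodendrocyte microRNAs 1 rose and 2 fell, or 1 and 3 adjusted over the list alone, with miR-338-3p at -1.13 ± 0.26.

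Of 13 microRNAs reported to target the serotonin transporter 4 rose and 2 fell, and of 11 reported to target the glucocorticoid receptor, 1 rose and 3 fell. Of 22 activity-regulated microRNAs 5 rose and 4 fell, of 23 let-7 and miR-98 members 8 rose and 4 fell, and of 17 miR-29 and miR-30 members 3 rose and 3 fell. In the Dlk1-Dio3 locus 12 of 59 miR-379/miR-410 members rose and 15 fell, and 3 of 20 miR-127/miR-433 members rose and 7 fell. Of 13 miR-17/92 and paralogous members 2 rose and 4 fell, and of 5 red blood cell microRNAs 2 rose and 1 fell (3 and 1 adjusted over the list alone). Of 8 Htr2c intronic microRNAs 1 rose, of 5 members of the miR-200 family and miR-183 cluster 1 rose, of 5 muscle microRNAs 1 fell, and the 1 hindbrain and spinal cord microRNA tested was not called.

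With corticosterone 136 microRNAs rose and 93 fell among 547 tested (edgeR quasi-likelihood, adjusted p below 0.05). The groups did not overlap for 77 of the 547, where chance gives 0.117% of them. Camera called no list (lowest adjusted p 0.497, with 0 lists under an unadjusted p of 0.05) and fry called 3. Within libraries of code letter G 135 microRNAs were called, where miR-132-3p was no longer called (0.31, adjusted p 0.145). Code letter H held 1 treated library, and no fit was run within it. With the axis of within-group variation as a covariate 25 rose and 14 fell, 31 of the 229 calls remained, and miR-132-3p lost its call (0.32 ± 0.24). In that fit miR-34c-3p (-1.27), miR-764-5p (-0.48), miR-126a-3p (-0.12) and miR-138-5p (-0.000302) had the opposite sign, none of them called. Without scaling factors 101 of 224 calls were rises, as the median log2 fold change of all microRNAs moved from 0.06 to -0.07. The call of miR-30d-3p was lost without WT-corticosterone 1 (-1.10, adjusted p 0.0625), and those of miR-34a-5p and miR-34c-3p in 9 and 7 of the fits that left out 1 library. The change of miR-34a-5p was 0.20 without WT-water 6, and that of miR-132-3p 0.38 without WT-corticosterone 6, where it kept its call (adjusted p 0.0291).

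In KO mice, exercise was tested between 5 KO-exercise and 6 KO-water libraries, and 21 microRNAs passed. MiR-132-3p rose from 2371 ± 484 to 4125 ± 551 CPM (log2 fold change 0.80 ± 0.17, 5 of 5 libraries above all KO-water libraries), while miR-212-3p had a log2 fold change of 0.43 ± 0.16 that did not pass (adjusted p 0.213 by edgeR). MiR-146a-5p rose from 77.0 ± 29.5 to 201 ± 21 CPM (1.38 ± 0.26). The related miR-99a-5p and miR-100-5p fell, miR-99a-5p from 14945 ± 4224 to 5029 ± 1741 CPM (-1.57 ± 0.27) and miR-100-5p by 1.39 ± 0.24 on the log2 scale. Present in every KO-exercise library and near 0 in KO-water were miR-126b-5p (575 counts against 1, ratio of rates 809, 95% counting interval 144.7 to 32026), miR-122b-3p (1078 against 25, ratio 60.7, 40.9 to 94.2) and miR-196b-5p (111 against 1, ratio 156, 27.5 to 6227).

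The remaining calls were rises of miR-3059-5p (2.05), miR-130a-3p (1.18), let-7b-3p (1.04), let-7d-3p (0.94), miR-669a-3p (0.90), miR-26b-5p (0.84), miR-335-5p (0.80), miR-873a-5p (0.78), miR-30c-5p (0.75), miR-324-3p (0.68) and miR-142a-3p (0.59), and falls of miR-93-3p (-1.12), miR-150-3p (-1.04) and miR-103-3p (-0.78). The adjusted p of all 21 calls lay between 7.04e-08 and 0.0443 (edgeR). By list, 2 of 22 let-7 and miR-98 members rose (5 adjusted over the list alone), 2 of 22 activity-regulated microRNAs rose, and 2 of 9 microglia and immune cell microRNAs rose and 1 fell (3 and 1 adjusted over the list alone). Of the vessel microRNAs 1 of 10 rose (miR-126b-5p), of miR-29 and miR-30 members 1 of 16, and of hindbrain and spinal cord microRNAs 1 of 2 (miR-196b-5p). Of 12 miR-17/92 and paralogous members 1 fell. In these and the following lists the other counts were the same adjusted over the list alone. No member was called among 26 neuron-enriched, 9 oligodendrocyte, 57 miR-379/miR-410, 20 miR-127/miR-433, 16 choroid plexus and ciliated cell, 8 Htr2c intronic, 7 miR-34 family, 6 miR-200 family and miR-183 cluster, 5 red blood cell and 3 muscle microRNAs. The same held for 13 microRNAs reported to target the serotonin transporter and 11 reported to target the glucocorticoid receptor.

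Of 523 microRNAs tested in KO mice with exercise, 16 rose and 5 fell (edgeR quasi-likelihood, adjusted p below 0.05), with 38 calls by DESeq2 and 20 by limma-voom. The groups did not overlap for 30 of the 523, where chance gives 0.433% of them. Camera called no list (lowest adjusted p 0.0650, 2 lists under an unadjusted p of 0.05) and fry called 1. That was the vessel list, with a median log2 fold change of 0.04 and a mean of 0.93, in which only miR-126b-5p was called. Within code letter G 3 microRNAs were called and within code letter H 1. With DESeq2's size factors 15 rose and 9 fell, and without a filter on low counts 11 were called. Calls rose to 121 with the axis of within-group variation as a covariate, to 177 against the 3 KO-water libraries of the genotype table and to 118 against the other 3. Without KO-exercise 4, 13 were called. Over all fits that left out 1 library 10 of the 21 kept their call in each, while miR-132-3p lost it without KO-water 1 (adjusted p 0.0509) or KO-exercise 2, 3 or 4 (0.0591, 0.0954 and 0.0597). The call of miR-30c-5p ended without KO-exercise 2 (adjusted p 0.0533), that of miR-103-3p without KO-exercise 4 (0.0557) and that of let-7b-3p without KO-exercise 4 or 5 (0.0827 and 0.0506). Those of miR-324-3p, miR-26b-5p, miR-150-3p, miR-669a-3p, miR-130a-3p, miR-873a-5p and miR-142a-3p ended in 3, 4, 6, 6, 7, 8 and 10 of these fits. Without KO-water 5 miR-212-3p passed (0.54, adjusted p 0.0431).

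For corticosterone in KO mice, 2 treated libraries stood against 6 KO-water libraries. MiR-126b-5p had 315 counts against 1 (ratio of rates 1037, 95% counting interval 184.8 to 41085), miR-122b-3p 569 against 25 (ratio 74.9, 50.2 to 117) and miR-196b-5p 59 against 1 (ratio 194, 33.5 to 7800). These 3 were the only calls by edgeR, with adjusted p of 0.000115, 0.00523 and 0.000468. MiR-132-3p had a log2 fold change of 0.44 ± 0.24 that did not pass (adjusted p 0.770), and neither did miR-100-5p (-1.31 ± 0.29), miR-99a-5p (-1.31 ± 0.35), let-7d-3p (0.97 ± 0.24), miR-3059-5p (2.05 ± 0.55), miR-103-3p (-0.94), miR-7a-1-3p (-0.94) and miR-1839-5p (-0.78), which had the smallest p among the rest.

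The miR-200 family and miR-183 cluster, microRNAs of epithelia and sensory tissue, was the 1 list called by camera in this comparison. None of its 7 tested members was called alone, their median log2 fold change was 1.26, and adjusted p was 0.0151. With an estimated correlation adjusted p = 0.555, with the code letter as a covariate 0.213 and with fry 0.269, and it was 0.963 without KO-corticosterone 1 and 0.208 without KO-water 1, 0.0646 without KO-water 2, 0.0553 without KO-water 5 and 0.0858 without KO-water 6. Of 10 vessel microRNAs and of 2 hindbrain and spinal cord microRNAs 1 each rose (miR-126b-5p and miR-196b-5p). No member was called of the lists of 26 neuron-enriched, 22 activity-regulated, 10 oligodendrocyte, 9 microglia and immune cell, 5 red blood cell, 5 muscle, 17 choroid plexus and ciliated cell, 9 Htr2c intronic, 59 miR-379/miR-410, 20 miR-127/miR-433, 23 let-7 and miR-98, 14 miR-17/92 and paralogous, 7 miR-34 family and 18 miR-29 and miR-30 microRNAs, nor of 14 reported to target the serotonin transporter and 11 reported to target the glucocorticoid receptor. These counts were the same adjusted over the list alone.

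Of 576 microRNAs tested, 3 rose and 0 fell by edgeR, 40 had an unadjusted p under 0.05, limma-voom called 3 and DESeq2 7. The groups did not overlap for 71 of the 576 microRNAs, where chance gives 7.14% of them, and the excess was not tested. Both KO-corticosterone libraries carried code letter H, and against the 2 KO-water libraries of that letter edgeR called 0 (7 at an unadjusted p under 0.05). MiR-122b-3p lost its call without KO-corticosterone 1 (adjusted p 0.106). There were 56 rises and 48 falls against the 3 KO-water libraries of the genotype table, 20 and 20 against the other 3 and 18 and 11 with the axis as a covariate.

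**Figure D3:**
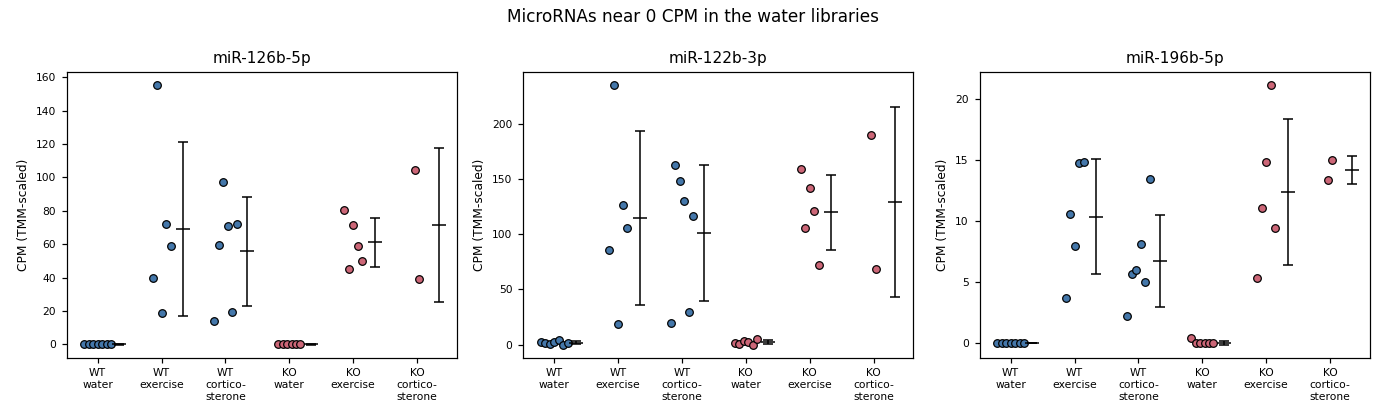
CPM (TMM-scaled over all libraries, vertical axis) of miR-126b-5p, miR-122b-3p and miR-196b-5p in each library of the 6 groups (horizontal axis), with points for libraries and lines for the mean and SD. All 18 exercise and corticosterone libraries held counts of each, while counts of miR-126b-5p were present in 2, of miR-122b-3p in 11 and of miR-196b-5p in 1 of the 13 water libraries, at low levels.

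The dependence of the exercise effect on genotype was tested as an interaction over 571 microRNAs. The KO effect minus the WT effect was -0.40 ± 0.21 on the log2 scale for miR-132-3p and -0.39 ± 0.19 for miR-212-3p, and neither passed (adjusted p 0.311 and 0.281 by edgeR). No microRNA was called by edgeR (101 at an unadjusted p under 0.05, lowest adjusted p 0.190), none by limma-voom and 4 by DESeq2, and 1 was called by edgeR without WT-exercise 2. For corticosterone, the interaction over 630 microRNAs gave 0 calls by edgeR (65 at an unadjusted p under 0.05, lowest adjusted p 0.447), 0 by DESeq2 and 0 by limma-voom.

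Exercise effects in WT and KO mice had a Pearson correlation of 0.656 and a Spearman correlation of 0.393 across 520 microRNAs, which are not independent replicates. MiR-126b-5p (ratios of rates 722 in WT and 809 in KO) and miR-122b-3p (57.3 and 60.7) were among them. Such large changes weigh on a Pearson correlation, which was not computed without them. The correlation of differences in mean log2 CPM was 0.517, and 15 of 100 shuffles of the group labels gave a value as far from 0. In both genotypes 14 microRNAs rose, against 3.14 for independent lists: miR-132-3p, miR-30c-5p, miR-26b-5p, miR-3059-5p, miR-324-3p, miR-142a-3p, let-7d-3p, let-7b-3p, miR-122b-3p, miR-669a-3p, miR-126b-5p, miR-130a-3p, miR-873a-5p and miR-335-5p. MiR-93-3p and miR-150-3p fell in both, against 0.654 for independent lists. Of these shared calls, miR-126b-5p, miR-122b-3p, miR-3059-5p, let-7b-3p, miR-873a-5p and miR-150-3p parted all treated libraries, corticosterone included, from all water libraries. A batch shared by the water libraries would also give such calls in both genotypes. Corticosterone effects had a Pearson correlation of 0.629 and a Spearman correlation of 0.381 across 545 microRNAs, again with miR-126b-5p and miR-122b-3p among them. For differences in mean log2 CPM the correlation was 0.528, with 17 of 100 shuffles as far from 0. MiR-126b-5p and miR-122b-3p rose in both genotypes, against 0.499 for independent lists.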

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

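The tests of library depth, of GC content, of the Dlk1-Dio3 cluster and of other splits of the 4 tested comparisons and the exercise interaction were chosen before the results they measure were seen, and every other test in this part was chosen after. Values of the named microRNAs were examined for a library far from the rest of its group, in 440 groups of values. In 29 of them the highest or lowest library stood apart by Dixon's test, and chance gives about 1 in 20.

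In WT-corticosterone 2 miR-219a-5p was 1621 CPM (others 114 to 540.2), miR-339-5p 146.8 (56.29 to 88.43), miR-434-3p 14250 (3000 to 6791) and miR-7a-1-3p 236.9 (136.3 to 164.8). In WT-exercise 1 miR-677-3p was 127.8 CPM (others 27.56 to 44.42), miR-677-5p 128.4 (27.03 to 44.93), miR-3059-5p 91.83 (45.95 to 55.09) and let-7a-2-3p 8.686 (1.532 to 3.18). WT-exercise 3 held 12820 CPM of miR-126a-3p (others 5438 to 7411) and 29.42 of miR-145b (9.307 to 13.46). In WT-water 1 miR-132-3p was 3394 CPM (others 2349 to 2634), miR-150-3p 59.3 (31.49 to 39.5), miR-18a-5p 151.6 (99.72 to 117.9) and miR-434-3p 10450 (8640 to 9412). WT-water 6 was low in miR-152-3p, 40.4 CPM (65.47 to 83.36), and high in miR-23b-5p, 82.59 (15.53 to 40.97), and miR-3084-3p, 57.04 (22.59 to 37.01). MiR-421-3p was low in WT-water 7, 91.15 CPM (120.6 to 142.1), and miR-574-5p high in WT-corticosterone 4, 3.734 (0 to 1.203).

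Among KO libraries, KO-water 5 had 994.6 CPM of miR-1298-5p (others 6.483 to 181.4), 32.51 of miR-1298-3p (8.623 to 13.64) and 1561 of miR-212-3p (967.2 to 1187). KO-exercise 2 had 100.6 CPM of miR-182-5p (3.195 to 9.728), KO-exercise 5 had 23.54 of miR-331-3p (10.86 to 12.41), and KO-exercise 1 had 633.1 of miR-219a-5p (175.6 to 289.6) and 4.26 of miR-574-5p (0.5717 to 1.255). The few water counts of miR-126b-5p came from WT-water 4 (0.4615 CPM) and KO-water 3 (0.5197), and that of miR-196b-5p from KO-water 1 (0.4133), with 0 in the other libraries of each group.

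The 6 KO-water libraries fell into 2 sets: between the 3 in the table of the genotype comparison and the other 3, edgeR called 290 microRNAs, among them miR-219a-5p (-3.72 ± 0.22) and miR-342-3p (2.35 ± 0.16). The tables argue against depth as counting noise alone, since 262 of the calls remained with every library thinned to 1277046 counts. Thinning keeps each microRNA's share of the counts, so a cause that goes with depth and changes these shares was not tested. On the axis of within-group variation, described below, the library with the lowest total scored highest in KO-water, WT-exercise and KO-exercise. In WT-corticosterone the library with the highest total did. The tables also argue against the code letter, since 1 of the 3 libraries in the table carried H and the other set also held 1. They argue against transcription of the Dlk1-Dio3 cluster as 1 unit, since 62.3% of its 77 members had the sign of their median. A gradient shared with treated WT libraries is a candidate explanation: across 532 microRNAs the difference had a Pearson correlation of 0.796 with the first axis of variation inside WT-exercise and WT-corticosterone. GC content stays open (r 0.188 over 504 microRNAs with the GC percent of the part of the hairpin that carries the arm, not of the mature sequence, under the bound of 0.2 set in advance but not by more than its spread), as do wrong genotype labels, which no counted RNA can test (0 calls between the other 3 libraries and WT-water by edgeR, 24 at an unadjusted p under 0.05), and a biological difference among the KO mice was not tested. The 10 splits of 3 against 3 libraries are too few for a share under 0.05, with 290 calls in the real split and 0 as the highest other.

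A separate axis, the first one drawn from all 6 groups and so including the KO-water sets themselves, held 38.8% of the variance inside groups. Scores on it were -9.26 ± 0.75 in WT-water (SD, n = 7), but ranged from -11.7 to 14.5 in WT-exercise, from -9.46 to 9.58 in WT-corticosterone and from -8.81 to 17.6 in KO-water. KO-water 1 and 2, WT-exercise 1 and 2 and WT-corticosterone 2, with consecutive code numbers within letter G, scored from -11.7 to -8.45, near WT-water. Outside WT-water, the libraries with the next numbers below and above, WT-corticosterone 1 and KO-water 3, scored 9.29 and 11.9. Whether the code number marks an order of processing was not tested. With the axis as a covariate, 24 of 180 WT exercise calls and 31 of 229 WT corticosterone calls remained, and the median absolute log2 fold change of the calls went from 0.87 to 0.39 (median SE 0.23 and 0.19) and from 0.77 to 0.35 (0.19 and 0.23). Most of these calls may therefore follow a gradient that not every treated library shows. A response to treatment that varies between mice would also enter the axis, since it was drawn from the same libraries. The scores kept the differences between group means, so a response along the axis common to all treated mice would be adjusted for as well. Tissue sampling, RNA handling and treatment response therefore stay open. Between the 2 KO-water sets the arms of some hairpins moved in opposite directions (miR-340-5p -1.55 and miR-340-3p 1.36, miR-708-5p 1.48 and miR-708-3p -1.44). Those of others moved together (miR-544-5p -2.45 and miR-544-3p -2.20, miR-22-5p -1.45 and miR-22-3p -1.68). A change in the amount of the hairpin alone would not part its arms, so it cannot by itself account for the first kind. Hairpins of each kind were not counted, and effects of sequence other than GC content were not tested. For WT exercise and WT corticosterone the real groups gave more calls than any other split, 180 against 112 and 229 against 93 (1 of 100 splits each). The high counts in other splits point to a structure among the libraries. With such a structure the splits do not exclude chance for these calls, nor do they part treatment from the gradient.

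MiR-126b-5p, miR-122b-3p and miR-196b-5p were present in 18 of 18 treated libraries and near 0 in 13 water libraries, with pooled ratios of rates of 706 (95% counting interval 241 to 3427), 56.7 (44.5 to 73.3) and 338 (60.3 to 13393). The tables argue against strandless counting in treated libraries, since 0 of 22 other microRNAs overlapping an abundant hairpin showed the pattern, and against a constant misassignment of miR-126a reads, since miR-126b-5p was 0.858% of miR-126a-3p counts in treated and 0.00137% in water libraries. Across treated libraries miR-122b-3p had a Pearson correlation of 0.934 with miR-126b-5p (Spearman 0.907, 0.909 without the 2 most extreme, 0.932 within G and 0.961 within H; adjusted p 4e-05, the smallest the permutations can give over 4 relations). In the same family of tests miR-126a-3p had a correlation of -0.611 (adjusted p 0.014, -0.213 within H), miR-196b-5p 0.247 and miR-122-5p 0.0796, neither of which passed. A batch shared by the water libraries and a biological response common to exercise and corticosterone cannot be told apart, as no label gives the sequencing pool of a library. Both code letters occur among water and among treated libraries, so the letter does not mark such a batch. For 6 microRNAs every treated library lay above every water library: miR-126b-5p, miR-122b-3p, miR-196b-5p, miR-3059-5p, let-7b-3p and miR-873a-5p. For 1, miR-150-3p, every treated library lay below (at most 20.5 against at least 21.0 CPM by library totals). All of these but miR-196b-5p were also exercise calls shared by both genotypes, so they fall under the same open question.

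For the 3 KO-water libraries of the genotype table against WT-water chance can be excluded, with 354 calls against 6 in the highest other split (1 of 100). This holds for those libraries only and does not separate genotype from the 2 sets of KO-water libraries. For exercise in KO mice 3 of 100 splits gave as many calls as the real 21, a share under the bound set in advance. The highest other split gave 101, several times the real count, which points to a structure among the libraries. With such a structure the splits do not exclude chance for these 21 calls. For the exercise interaction the splits decide nothing, since any split gives at least the 0 calls of the real one (100 of 100, highest other 13).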

How the results depend on the processing

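Other sets of KO-water libraries and the axis as a covariate were chosen after the results were seen, and the other alternatives were planned. Where no reason is given, the cause was not tested.

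The genotype comparison depended most on which libraries stood for KO-water. Its 354 calls became 69 in a joint fit of all 6 groups, which also holds all KO-water libraries, 0 with all 6 KO-water libraries in a separate fit (179 at an unadjusted p under 0.05), 0 with only the 3 outside the table (24) and 0 with all 6 and the axis (23), all by edgeR. With the 3 outside libraries the sign reversed for miR-182-5p (-0.13), miR-145b (-0.0642), miR-503-3p (-0.00111), miR-223-3p (-0.31), miR-135a-5p (-0.32), miR-9-5p (0.15), miR-29b-3p (0.36), miR-486a-5p (-0.0175) and miR-126a-3p (-0.0785). With all 6 and the axis it reversed for miR-182-5p (-0.31), miR-145b (-0.14), miR-152-3p (-0.0259), miR-421-3p (-0.0099), miR-503-3p (-0.14), miR-223-3p (-0.39), miR-450a-5p (0.00456), miR-362-5p (0.10), miR-135a-5p (-0.37), miR-9-5p (0.16), miR-124-3p (-0.00697), miR-29b-3p (0.40), miR-434-3p (0.0467), miR-486a-5p (-0.0668) and miR-126a-3p (-0.13). Over these and the other alternatives 428 values of named microRNAs kept direction and side of the threshold, 24 reversed, and the rest no longer passed. Leaving out 1 library gave 308 to 361 calls.

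For exercise in WT mice the 180 calls became 38 with the replicate number as a block and 27 with the axis, where miR-325-5p reversed (-0.32). They became 10 within code letter G, against 210 within code letter H, a fit of 2 exercise and 2 water libraries. Values of named microRNAs stayed the same in 395 cases, no longer passed in 93 and reversed in 1. Leaving out 1 library gave 1.0e+02 (66 up and 37 down, without WT-exercise 5) to 274 (without WT-exercise 2).

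For corticosterone in WT mice the 229 calls became 135 within code letter G and 39 with the axis, where miR-764-5p (-0.48), miR-34c-3p (-1.27), miR-138-5p (-0.000302) and miR-126a-3p (-0.12) reversed. MiR-212-3p, not past the threshold, changed sign with library sizes only (-0.0105). In 380 cases values stayed the same, in 41 they no longer passed and in 5 they reversed. Leaving out 1 library gave 172 to 292 calls.

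For exercise in KO mice the 21 calls became 38 with DESeq2, 11 without a filter on low counts, 40 in the joint fit, 8 with the replicate block, 3 within code letter G, 1 within code letter H, 121 with the axis, 177 against the KO-water libraries of the genotype table and 118 against the others. None of the named microRNAs reversed, 261 values stayed the same, 66 no longer passed and 2 newly passed. Leaving out 1 library gave 13 (without KO-exercise 4) to 29 calls.

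For corticosterone in KO mice the 3 calls became 7 with DESeq2, 8 in the joint fit, 78 with the replicate block, 0 within code letter H (edgeR, 7 at an unadjusted p under 0.05), 29 with the axis, 1.0e+02 (56 up and 48 down) against the KO-water libraries of the genotype table and 40 against the others. No named value reversed, 4 no longer passed, 26 newly passed and the rest stayed the same. With the replicate block, treatment was compared only within the 2 replicate numbers that both groups hold. Leaving out 1 library gave 2 to 3 calls, with 1 treated library then assumed to vary like the other group.

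Fry in place of camera called 13, 3, 3 and 1 lists in the genotype, WT exercise, WT corticosterone and KO exercise comparisons. For KO corticosterone the 1 called list became 0 with estimated correlations, 0 with fry, 8 with the replicate block (2 shared replicate numbers) and 0 with the code letter. Leaving out 1 library gave 0 to 0 lists in the first 3 comparisons, 0 to 2 for KO exercise (2 without KO-water 2, 1 without KO-exercise 2) and 0 to 3 for KO corticosterone (3 without KO-corticosterone 1). The exercise interaction had 0 to 1 calls without 1 library (1 without WT-exercise 2) and 4 with DESeq2, and the corticosterone interaction 0 to 0. Correlations between the genotypes' effects at a mean of at least 10 CPM were 0.683 for exercise and 0.683 for corticosterone, against 0.656 and 0.629.

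Replicate numbers did not pair libraries: correlations of libraries with the same number lay between -0.301 and 0.496, so block results rest on a shared number alone. Fits within code letter H for the genotype and WT corticosterone comparisons, and within G for KO corticosterone, were not run. Within H the KO-water and WT-corticosterone groups of these comparisons held 1 library each, and within G KO-corticosterone held 0. On simulated counts 40.3% of 1.5-fold changes were recovered in the genotype comparison, 45.5% in WT exercise and 47.6% in WT corticosterone. In KO exercise 28.4% were recovered and in KO corticosterone 4.48%. Small changes could therefore not be excluded in any comparison, least of all in the last.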

Other observations

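The direct contrasts, the axis fits and the exact permutation tests in this part were chosen after the main results were seen. A choroid plexus microRNA and 2 from Htr2c introns, chosen after their values were seen, varied widely inside some groups and less in others. MiR-204-5p was 9633 ± 6323 CPM in WT-water (4746 to 20393, n = 7) and 12925 ± 8350 in WT-corticosterone (5216 to 26139, n = 6), against 5826 ± 1461 in WT-exercise (4405 to 8186, n = 5) and 5697 ± 461 in KO-exercise (5114 to 6199, n = 5). MiR-1298-5p, from an Htr2c intron, ranged from 63.2 to 1444 CPM in WT-water and from 23.9 to 119 in WT-exercise, and in KO-water from 6.48 to 995, and miR-448-3p, from the same gene, ranged from 5.36 to 57.9 in WT-water and from 3.61 to 85.2 in WT-corticosterone, against 5.32 to 14.4 in KO-exercise.

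Exercise and corticosterone libraries were also set against each other. Between WT-exercise and WT-corticosterone edgeR called 0 of 521 microRNAs (20 at an unadjusted p under 0.05), and 1 with the axis as a covariate (35), which was miR-212-3p. Without the axis the splits decide nothing about chance, since any split gives at least 0 calls (100 of 100), and the highest other, 251, points to a structure among the libraries. With the axis chance cannot be excluded for the number of calls, as 1 call stood against 26 in the highest other split and 9 of 100 splits gave as many. Between KO-exercise and WT-exercise there were 0 calls of 517 (5 at an unadjusted p under 0.05), or 0 with the axis (31), where the splits decide nothing either, with 2 and 4 calls in the highest others. KO-exercise against KO-corticosterone gave 0 calls of 550 (13, and 0 with 23 using the axis), and KO-corticosterone against WT-corticosterone 0 of 552 (9, and 0 with 12), all by edgeR, the only tool run for these contrasts.

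A hypothesis is that exercise raises the miR-132/miR-212 transcript by more than corticosterone does. With the axis as a covariate the WT exercise change of miR-132-3p was 0.99 ± 0.14 on the log2 scale against 1.13 ± 0.14 without, so the gradient did not account for it, and that of miR-212-3p was 0.73 ± 0.12. Against WT-corticosterone, miR-212-3p was 0.66 ± 0.10 higher with the axis (adjusted p 0.00465, edgeR) but missed the threshold without it (0.66 ± 0.13, adjusted p 0.107), and miR-132-3p passed in neither (adjusted p 0.230 and 0.740). In CPM by library totals the lowest WT-exercise value of miR-212-3p, 2027, lay above the highest WT-corticosterone value, 1497 (5 of 5 above 6 of 6, exact permutation p 0.00216, adjusted 0.00289 over 4 tests), and for miR-132-3p p was 0.00866. It remains a hypothesis, since the contrast was chosen after the results were seen and the fit without the axis missed the threshold. The splits given above count calls of any microRNA and do not bear on miR-212-3p itself. In KO mice miR-212-3p had a difference of 0.52 ± 0.18 between exercise and corticosterone (adjusted p 0.998, n = 5 and 2), and neither microRNA passed the interaction with genotype.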
